A study of Sus scrofa with 24 samples.

How the data were processed

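Liver RNA of 24 pigs (Sus scrofa) at 115 kg body weight was measured, 1 array per pig, in 3 groups of 8. The groups were a line selected for low residual feed intake (RFI) fed ad libitum, a line selected for high RFI fed ad libitum, and pigs of the high RFI line restricted to the feeding level of the low RFI line. Groups and pig numbers were taken from the labels, which describe 8 pigs per condition.

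Per the labels' protocols, 150 ng of total RNA per pig was amplified and labelled with the dye Cy3. Per the file headers, each array was a 1-colour Agilent design with 45220 features, of which 1417 were controls, read by Agilent Feature Extraction 10.7.3.1. The deposited intensity values used here are the scanner software's processed signal, from which, per the file headers, a fitted background surface had been subtracted and to which a multiplicative detrending had been applied. The mean pixel intensity of each spot and the median of its local background, also in the deposited scanner output, served only for an alternative background correction. Further deposited columns marked each spot as well above background, saturated, or an outlier with 0 or 1. The submitters' processing notes name R 2.10.0.

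The authors also deposited a table of log2 values for 27564 features. Set against the scanner output, every column equalled log2 of the processed signal minus the array's median over those features, with a correlation of 1 and a column median of 0 on each of the 24 arrays. How those features were chosen is not given in the sources used here.

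From the scanner output, control spots were left out, which left 43803 spots. The processed signal was put on the log2 scale, the 75th percentile of each array was subtracted, and spots of the same probe were averaged, which gave 43603 probes. A probe was kept where it was well above background on at least 6 of the 8 arrays of at least 1 group, and 29665 probes were kept. All levels are log2 values relative to the 75th percentile of the array, and all differences are differences of their group means.

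Probes were named through the accession, gene identifier or symbol given in the scanner output, matched to tables of pig gene names and of the RefSeq annotation of Sscrofa11.1, which was used for names only. A single symbol was found for 12241 of the 43603 probes, covering 5390 symbols. Of these, 7185 matched through a RefSeq accession, 1367 through a gene identifier, 3417 through a symbol or synonym and 96 through a gene name in the description, and 176 kept the name in the scanner output. A further 29 probes matched several genes and 31333 were left unnamed. No genome was used, so no positions are given.

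Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with group as the only factor and all 24 arrays in the fit, and with Benjamini-Hochberg adjustment over the 29665 probes. An adjusted p below 0.05 was the threshold. The comparisons were high minus low RFI (both fed ad libitum), restricted high minus high RFI (the same line at different feeding levels), restricted high minus low RFI (different lines at the same feeding level), and a moderated F test over the 3 groups. The deposited tables were read with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6) and data.table (1.17.8), and plots were drawn with matplotlib 3.10.9.

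Gene lists were tested with camera in limma at a preset correlation of 0.01, on 1 probe per gene (the one with the highest mean signal), over 4493 genes, with Benjamini-Hochberg adjustment over 48 lists within each comparison. Of the lists, 32 held pathways and 16 held markers of cell types or tissues. An estimated correlation and fry were run beside it. Camera compares a list with the other genes. Fry asks only whether the genes of a list move, on balance, in the same direction.

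Low minus high and restricted minus high differences share the high RFI arrays. Their covariance and correlation across probes were therefore set beside 1000 simulated unchanged groups against those arrays, and beside all 70 ways to split the 8 high RFI arrays into sets of 4, so that the differences shared no array. The other pairing, with the low RFI arrays shared, was treated likewise, and the overlap of its called probes was set beside 100 simulated sets of 3 unchanged groups, drawn from the residual arrays with replacement. Both were repeated with each group drawn from its own residual arrays and the numbers of high and restricted pigs drawn together or apart. These repeats, the overlap test and the test of whether same-numbered pigs deviate together (all 40320 renumberings of the 8 pigs of a group) were added after the data were seen.

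The genes named in the text follow a rule fixed before the data were examined, as were the gene lists, the tests and all alternatives except those described as chosen later. In each comparison, up to 10 genes with the largest difference in each direction are named among probes past the threshold that carry 1 symbol, each by its probe with the smallest p. Where none passed, the 10 genes with the smallest p are given as values. Of a gene list, up to 4 members with the smallest p are named, each by its probe with the highest signal. Not every gene that met this rule is described here. No named gene had probes that differed in opposite directions past an unadjusted p of 0.05. A probe that was not well above background on any array of a group has only a bound there. Its fold is given as at least the bright group's mean against, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

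The fit was tested on simulated data for the high minus low comparison with 29665 probes, of which 200 were changed. It recovered 39% of the 100 probes changed by 0.5 on the log2 scale and 82% of the 100 changed by 1. It made 0 false calls for restricted minus low. For restricted minus high, camera recovered a list shifted by 0.2 and called 0 other lists. The simulated genes varied independently of each other. The test therefore cannot show how often camera calls lists whose genes vary together.

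The 24 arrays lay on 6 slides of 4 arrays, and each slide held all 3 groups. They were scanned on 2 days with 3 slides each. Slide and scan day were tested as blocks and within each batch. Other alternatives were normexp background correction (offset 50, fitted with control spots included), quantile normalisation, median centring, the authors' deposited log2 values, no filter or a stricter filter on dim probes (well above background on all 24 arrays, 25720 probes), outlier spots left out, the pig number as a block, only the 2 groups compared, array weights, a trended and robust spread estimate, and for lists the mean of all probes of a gene. After the data were seen, 5 more were added. Of these, 4 left out arrays: high RFI pigs 5 and 7, restricted pigs 7 and 8, low RFI pigs 7 and 8, and the slide with the fewest spots above background. The other took the pig number as a block in a fit of the high and restricted high RFI pigs alone.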

Results

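The liver transcriptome was profiled in 24 pigs at 115 kg body weight, 8 in each of 3 groups. Residual feed intake (RFI) is the feed eaten beyond what is predicted from growth and maintenance, so low RFI pigs are the more feed-efficient line. Low RFI and high RFI pigs had free access to feed, and a further group of the high RFI line was held at the feeding level of the low RFI line. The design therefore separates a difference between lines at free intake, a difference in feeding level within the high RFI line, and a difference between lines at the same feeding level.

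Between 63.2% and 72.7% of the spots on an array were well above background. The share was 67.8% ± 2.77 in low RFI, 70.2% ± 2.28 in high RFI and 67.4% ± 2.81 in restricted high RFI pigs (SD, n = 8 each). Of the 6 slides, slide 3 had the smallest share of spots above background, at 63.9% ± 1.19 (SD, n = 4). Its signal was not the lowest, with a mean 75th percentile of 419.8 against 379.8 on slide 6. Correlations between arrays ranged from 0.971 to 0.991 over the probes kept, and no pair of arrays held identical values. The number of arrays limits the precision of each value below.

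High and low RFI pigs, both fed ad libitum, differed in a small set of liver transcripts. OAZ3 (probe A_72_P437459), which encodes an antizyme of ornithine decarboxylase, was 5.13-fold higher in high RFI pigs, at 0.31 ± 0.54 against -2.05 ± 0.95 on the log2 scale (SD, n = 8, adjusted p = 0.00271). UBD (probe A_72_P441035), a ubiquitin-like modifier, was 3.32-fold higher, at 1.07 ± 0.51 against -0.65 ± 0.53 (SD, n = 8, adjusted p = 0.000648). ZAR1L (probe A_72_P671850), related to an oocyte RNA-binding protein, fell by 2.07 (SE 0.28, adjusted p = 0.000956). In high RFI pigs its signal was dim, at -5.06 ± 0.28 (SD, n = 8), and well above background in 6 of 8.

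Among other dim transcripts, that of the tyrosine kinase gene SYK was higher by 1.05 ± 0.18 in high RFI pigs (SE, adjusted p = 0.00841). SYK was well above background in 3 of 8 low RFI pigs. Heparanase, HPSE, was not well above background in any low RFI pig and was at least 1.47-fold higher in high RFI pigs (adjusted p = 0.00375). Both HPSE and SYK turned slightly negative under normexp background correction, with differences of -0.065 and -0.034. Lower in high RFI pigs were C4H8orf37 (-1.01 ± 0.18, adjusted p = 0.0154) and the ADP receptor gene P2RY1 (-0.77 ± 0.16, adjusted p = 0.0497). So were STAT5A, a transducer of growth hormone signals (-0.44 ± 0.08, adjusted p = 0.0214), and the ribosomal protein gene RPL14 (-0.33 ± 0.06, adjusted p = 0.0237, all SE). In each of the genes named here, all 8 high RFI pigs lay on the same side of the low RFI mean. The genes were chosen from the same pigs, so this follows largely from that choice. HPSE and SYK each had 1 other probe, which in this comparison went the same way without passing an unadjusted p of 0.05, and UBD had no other probe. Of 16 alternatives, RPL14 lost its call in 7, among them slide as a block (-0.32). P2RY1 lost its call in 6, among them slide 3 left out (-0.84). STAT5A lost its call in 4, among them the pig number as a block (-0.44). C4H8orf37 and ZAR1L lost theirs under normexp only (-0.74 and -0.83).

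**Figure D1:**
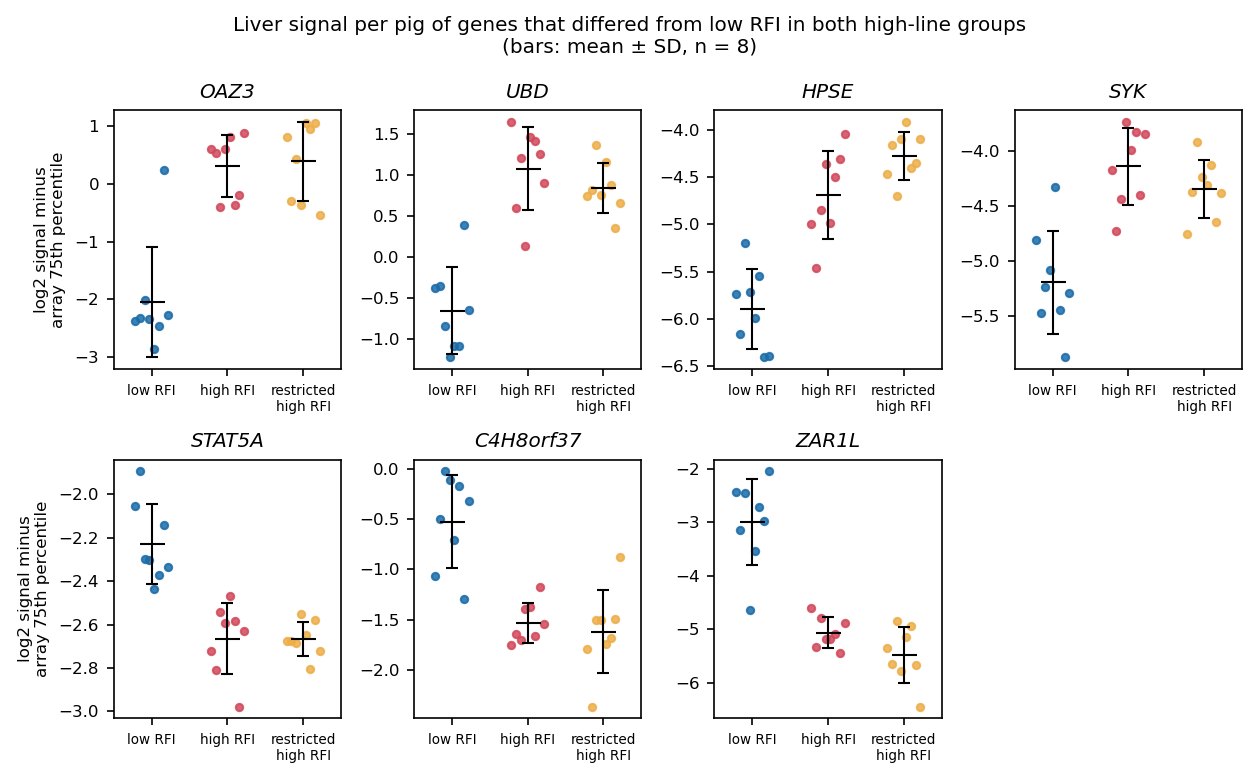
Each panel shows a gene that differed from low RFI pigs in both groups of the high RFI line, with the log2 signal relative to the array's 75th percentile on the vertical axis. Points are single pigs (8 per group), and bars are the mean and SD. OAZ3 averaged -2.05 in low RFI pigs, 0.31 in high RFI pigs and 0.39 in restricted high RFI pigs.

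In all, 48 of 29665 probes passed the threshold between high and low RFI pigs, 24 higher and 24 lower in high RFI pigs. Of these, 14 carried a symbol and represented 10 genes, and 34 were unnamed. Among these 48, the largest difference belonged to the unnamed probe A_72_P205617, higher by 4.27 ± 0.71 (SE), and the largest in the other direction to the unnamed probe A_72_P427894 (-3.58 ± 0.63). At an unadjusted p under 0.05 there were 2824 probes, where 1483 are expected by chance. With slide as a block 35 probes passed, with scan day as a block 43. On the separate scan days 4 and 8 passed, and on both days all 48 kept their direction. These probes were chosen from the same arrays, so their direction on each day is largely fixed by that choice. With normexp background correction 5 passed, 4 higher and 1 lower.

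Genes of fatty acid synthesis were higher as a list in high RFI than in low RFI liver. In this comparison 59 of 100 splits of the arrays, the real one included, called at least as many lists, as given below. The 13 measured members rose by 0.51 on average (camera adjusted p = 1.94e-05, adjusted p = 0.827 with an estimated correlation), with 11 members above 0. Of the members, 0 passed limma's threshold over all probes, 7 had an unadjusted p under 0.05, and 4 were higher when adjusted over the list alone. The differences were 1.13 ± 0.28 for malic enzyme ME1, which supplies NADPH, and 0.62 ± 0.22 for fatty acid synthase, FASN. They were 0.60 ± 0.23 for acetyl-CoA carboxylase, ACACA, and 0.42 ± 0.16 for the desaturase FADS1 (SE). The list's difference was 0.65 and 0.40 on the separate scan days and 0.52 with slide as a block. Without low RFI pigs 7 and 8, which had the lowest scores, it was 0.30. The share of spots above background was also highest in the high RFI group, as given above.

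Interferon-response genes, which act in antiviral defence, were higher on average in high RFI pigs, with the highest levels in 2 animals. The 30 measured members rose by 0.51 on average (camera adjusted p = 2.16e-08, adjusted p = 0.907 with an estimated correlation), 29 of them above 0. Of the members, 0 passed limma's threshold over all probes and 0 when adjusted over the list alone, with 7 at an unadjusted p under 0.05. They include GBP1 (0.64 ± 0.22), PSMB9 (0.69 ± 0.23), OAS2 (1.01 ± 0.39) and CXCL9 (0.99 ± 0.38, SE). High RFI pigs 5 and 7 had list scores of 1.74 and 1.96, and all other pigs lay between -0.62 and 0.51. Without these 2 pigs the mean of the list differed from low RFI by 0.00087, over members that went both ways. Of those named, GBP1 was then at 0.51, CXCL9 at 0.62, OAS2 at 0.53 and PSMB9 at 0.34, where CXCL11 was at -0.88 and OAS1 at -0.51. With slide as a block the difference was 0.58, and on the separate scan days it was 0.45 and 0.51.

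Ribosomal protein genes were slightly lower on average in high RFI than in low RFI pigs. The 47 measured members fell by 0.095 on average (camera adjusted p = 1.98e-07, adjusted p = 0.907 with an estimated correlation), 44 of them below 0. RPL14 passed the threshold over all probes and also when adjusted over the list alone. RPL5 (-0.23 ± 0.09) and RPL11 (-0.14 ± 0.06, SE) did not pass. The list's difference was -0.13 and -0.069 on the separate scan days and -0.090 with slide as a block. Under normexp background correction it was -0.014.

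Markers of stellate cells and fibroblasts were lower in high RFI pigs. The 14 measured markers fell by 0.25 on average (camera adjusted p = 0.014, adjusted p = 0.907 with an estimated correlation), and 12 lay below 0. The pericyte gene RGS5 differed by -1.10 ± 0.30, biglycan BGN by -0.29 ± 0.11, the collagen gene COL1A2 by -0.46 ± 0.20 and SPARC by -0.47 ± 0.26 (SE). Of the markers, 0 passed limma's threshold over all probes, 3 had an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. The list was lower on all 6 slides, each with 1 or 2 pigs of a group, which follows partly from its choice on these arrays. It was lower by -0.33 and -0.17 on the separate scan days and by -0.30 with slide as a block. Without slide 3 it differed by -0.24 and did not pass. Markers of some other cells lay below 0 without passing, at -0.41 for neutrophils (6 of 6 below 0, adjusted p = 0.118), -0.11 for endothelium (9 of 11, adjusted p = 0.467), -0.15 for adipocytes (6 of 7, adjusted p = 0.604) and -0.67 for pancreatic acinar cells (3 of 4, adjusted p = 0.467), the last on all 6 slides.

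Feeding the high RFI line at the low RFI level changed no single transcript past the threshold. The 10 genes with the smallest p are given as values only. Genes of lipid synthesis and its control were the desaturases FADS1 (-0.95 ± 0.21, adjusted p = 0.702) and FADS2 (-0.71 ± 0.18, adjusted p = 0.717), and SCAP, which escorts the sterol-regulated transcription factors (0.35 ± 0.08, adjusted p = 0.702). Genes of the endoplasmic reticulum stress response were XBP1, its transcription factor (0.44 ± 0.09, adjusted p = 0.558), and the chaperone gene HSP90B1 (0.51 ± 0.13, adjusted p = 0.717). The chromatin protein gene HMGA1 had the smallest adjusted p (-0.45 ± 0.08, adjusted p = 0.131). The others were SHC1 (0.25 ± 0.06), RPL14 (0.23 ± 0.06), CD84 (-0.59 ± 0.16) and the histone gene H3F3A (0.35 ± 0.09, all SE, n = 8 per group). In each of these genes all 8 restricted pigs lay on the same side of the high RFI mean. The genes were chosen by p from these same pigs, so this is not separate evidence.

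Limma called 0 of 29665 probes between restricted high and high RFI pigs, with 1580 at an unadjusted p under 0.05, where 1483 are expected by chance. The count was also 0 with slide or scan day as a block. On the separate scan days it was 0 and 1. With array weights 2 probes passed.

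Between the feeding levels 7 gene lists passed camera's threshold at the preset correlation, and 0 passed with an estimated correlation or by fry. Of 100 splits of the arrays, the real one included, 36 called at least as many lists, as given below. The 13 genes of fatty acid synthesis fell by 0.38 on average under restriction, all of them below 0 (camera adjusted p = 1.02e-05, adjusted p = 0.254 with an estimated correlation). The acetyl-CoA synthetase gene ACSS2 differed by -0.82 ± 0.35, FASN by -0.47 ± 0.22 and the brightest FADS1 probe by -0.34 ± 0.16 (SE), beside FADS2. The 11 genes of the unfolded protein response rose by 0.23 (camera adjusted p = 2.17e-06, adjusted p = 0.254 with an estimated correlation), and 10 lay above 0. The endoplasmic reticulum co-chaperone genes DNAJB11 and SDF2L1 differed by 0.38 ± 0.13 and 0.49 ± 0.19 (SE), beside XBP1 and HSP90B1. Adjusted over the list alone, 1 fatty acid synthesis gene was lower and 2 unfolded protein response genes were higher. Over all probes, 0 members of either list passed limma's threshold, with 4 of each at an unadjusted p under 0.05.

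Both groups kept their direction on the separate scan days, at -0.48 and -0.25 for fatty acid synthesis and 0.23 and 0.26 for the unfolded protein response. With slide as a block they shifted by -0.36 and 0.20. The unfolded protein response was higher in restricted than in high RFI pigs on all 6 slides, and fatty acid synthesis was lower on 5 of 6. Each slide held 1 or 2 pigs of a group. The lists passed on these same arrays, so their directions by slide and day follow partly from that choice. Without restricted pigs 7 and 8, fatty acid synthesis differed by -0.26, which remained past camera's threshold.

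Ribosomal protein genes rose by 0.077 under restriction, 45 of 47 members being above 0 (camera adjusted p = 4.65e-07, adjusted p = 0.678 with an estimated correlation). Members RPL5 (0.19 ± 0.09) and RPL10A (0.16 ± 0.10, SE) did not pass. The 27 respiratory chain genes rose by 0.076 (camera adjusted p = 0.00205, adjusted p = 0.818 with an estimated correlation), with ATP5O at 0.23 ± 0.09, NDUFB6 at 0.17 ± 0.08, ATP5J2 at 0.12 ± 0.09 and NDUFA9 at 0.12 ± 0.09 (SE). The 20 acute phase protein genes rose by 0.21 (camera adjusted p = 0.0394, adjusted p = 0.678 with an estimated correlation). Among them were fibrinogen gamma FGG (0.34 ± 0.10), the lipopolysaccharide-binding protein gene LBP (0.68 ± 0.32), CRP (0.57 ± 0.27) and LCN2, which went the other way (-0.50 ± 0.23, SE). Without restricted pigs 7 and 8 the acute phase difference was 0.083, and without high RFI pigs 5 and 7 the respiratory chain and acute phase differences were 0.037 and 0.20. The acute phase list passed in neither case, and the respiratory chain did not pass in the latter. Without restricted pigs 7 and 8 the respiratory chain difference was 0.12, and under normexp it was 0.11 and the ribosomal difference 0.12.

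The 14 cell cycle genes fell by 0.40 under restriction, 13 of them below 0 (camera adjusted p = 3.04e-05, adjusted p = 0.678 with an estimated correlation). The replication genes MCM4 and MCM3 differed by -0.63 ± 0.31 and -0.71 ± 0.35, and the mitotic genes CDK1 and CCNB2 by -0.73 ± 0.36 and -0.53 ± 0.29 (SE). The 30 interferon-response genes fell by 0.40 (camera adjusted p = 1.31e-06, adjusted p = 0.678 with an estimated correlation), including IRF1 (-0.32 ± 0.14), PSMB9 (-0.47 ± 0.23), GBP1 (-0.44 ± 0.22) and STAT2 (-0.16 ± 0.09, SE). Without high RFI pigs 5 and 7 the mean of the list turned to 0.11, and without slide 3 it was -0.26. The cell cycle difference was -0.26 without restricted pigs 7 and 8 and -0.25 under normexp, and it passed in both. Of the ribosomal, respiratory chain, acute phase, cell cycle and interferon genes, limma called 0 over all probes and 0 when adjusted over the list alone, and 2, 1, 4, 0 and 1 had an unadjusted p under 0.05.

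On the separate scan days the ribosomal list differed by 0.10 and 0.050, the respiratory chain by 0.11 and 0.039, and acute phase proteins by 0.20 and 0.24. The cell cycle list differed by -0.61 and -0.081, and the interferon list by -0.53 and -0.25. With slide as a block the differences were 0.071, 0.072 and 0.24 for the ribosomal, respiratory chain and acute phase lists. They were -0.47 and -0.51 for the cell cycle and interferon lists. The respiratory chain did not pass with quantile normalisation (0.029) or array weights (0.054), nor did acute phase proteins with array weights (0.16).

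At the same feeding level OAZ3, UBD, HPSE, SYK, ZAR1L, C4H8orf37 and STAT5A again passed the threshold. Relative to low RFI pigs, restricted high RFI pigs had 5.41-fold more OAZ3 transcript, at 0.39 ± 0.68 against -2.05 ± 0.95 (SD, n = 8, adjusted p = 0.00152). UBD was 2.82-fold higher (adjusted p = 0.00185), SYK was higher by 0.85 ± 0.18 (adjusted p = 0.0398) and HPSE was at least 1.96-fold higher (adjusted p = 7.7e-05). Here the other probe of HPSE passed an unadjusted p of 0.05 in the same direction. Under normexp, HPSE and SYK again turned negative, at -0.071 and -0.18. ZAR1L fell by 2.48 (SE 0.28, adjusted p = 7.7e-05) and was well above background in 1 of 8 restricted pigs. C4H8orf37 was lower by -1.10 ± 0.18 (adjusted p = 0.00739) and STAT5A by -0.44 ± 0.08 (SE, adjusted p = 0.0204). Beside its reversal, SYK lost its call in 8 of 15 alternatives, among them scan day as a block (0.82). STAT5A lost its call in 6 of 17, among them the pig number as a block (-0.44). C4H8orf37 lost its call in 2, with only these groups in the fit (-1.10) and without slide 3 (-0.99).

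Further genes passed the threshold in this comparison. Arginase, ARG1, the last enzyme of the urea cycle, was higher in restricted high RFI than in low RFI pigs by 1.02 ± 0.20 (adjusted p = 0.0264), and the insulin-responsive glucose transporter gene SLC2A4 by 1.01 ± 0.20 (adjusted p = 0.0269). The guidance factor gene NTN1 was higher by 0.90 ± 0.16 (adjusted p = 0.0167), the cytochrome P450 gene CYP2C33 by 0.88 ± 0.18 (adjusted p = 0.0364) and the mitochondrial release factor gene MTRF1 by 0.64 ± 0.13 (adjusted p = 0.0372). Lower were the transcription factor gene KLF3 (-1.33 ± 0.27, adjusted p = 0.0338), the calcium-binding protein gene S100A4 (-0.84 ± 0.16, adjusted p = 0.0264), COQ3 of coenzyme Q synthesis (-0.68 ± 0.14, adjusted p = 0.0376) and NDUFAF3, an assembly factor of respiratory complex I (-0.43 ± 0.09, SE, adjusted p = 0.0364). In all 16 named genes the 8 restricted pigs lay on the same side of the low RFI mean, which again follows largely from choosing the genes in these pigs. KLF3, MTRF1, NDUFAF3 and SLC2A4 had other probes, none of which passed an unadjusted p of 0.05 in the same direction, and S100A4 had no other probe. ARG1, SLC2A4, CYP2C33, MTRF1, KLF3, S100A4, COQ3 and NDUFAF3 kept their direction but did not pass with slide as a block. Without slide 3, 11 of the 16 genes did not pass. Of 17 alternatives, NDUFAF3 lost its call in 9, MTRF1 and COQ3 in 8, ARG1 and CYP2C33 in 7, KLF3 and SLC2A4 in 6, S100A4 in 5 and NTN1 in 1. Whether these genes differed more at this feeding level than at free intake is the restricted minus high comparison, in which none of them passed.

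Of 29665 probes, 66 passed between restricted high RFI and low RFI pigs, 36 higher and 30 lower in restricted pigs. Of these, 20 carried a symbol and represented 16 genes. At an unadjusted p under 0.05 there were 3767. With slide as a block 51 passed, with scan day as a block 63, and on the separate scan days 33 and 7. All 66 had the same direction on both days, which their choice from these arrays largely fixes. Without slide 3, 24 passed, without restricted pigs 7 and 8 it was 25 and without low RFI pigs 7 and 8 it was 31. With only these groups in the fit 27 passed, and under normexp 13 passed, 10 higher and 3 lower. The moderated F test over the 3 groups called 63 probes, and 47 with slide as a block.

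**Figure D2:**
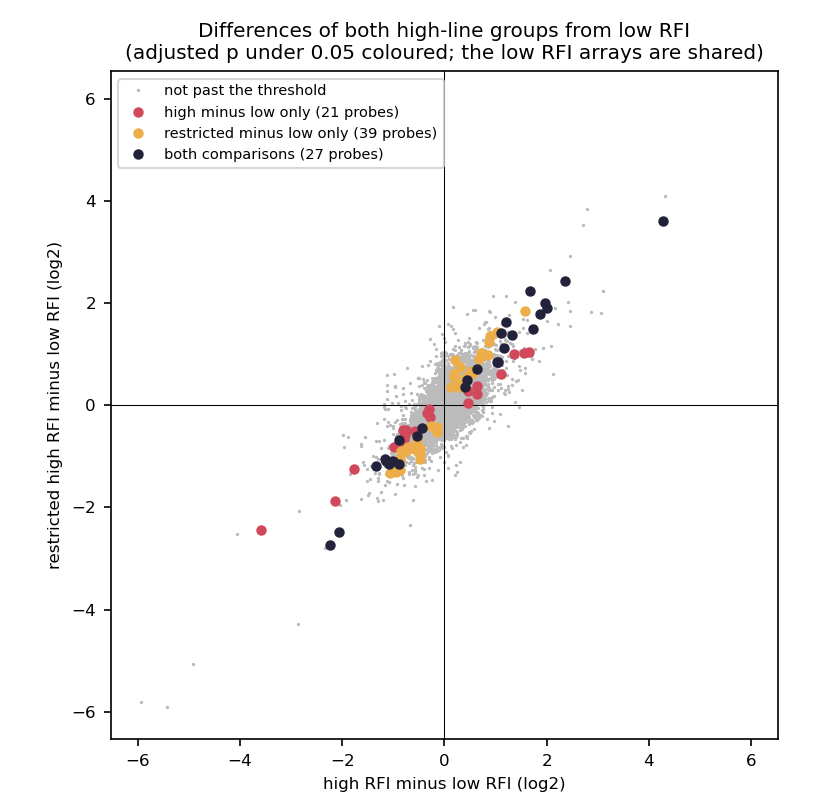
Each point is 1 of 29665 probes, with the log2 difference of high RFI from low RFI pigs on the horizontal axis and that of restricted high RFI from low RFI pigs on the vertical axis. Coloured points passed an adjusted p of 0.05 in at least 1 of these comparisons (87 probes, 27 of them in both), and all 87 have the same sign on both axes.

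Lists of secretory and stress chaperones were higher on average in restricted high RFI than in low RFI pigs. In this comparison 28 of 100 splits of the arrays, the real one included, called at least as many lists, as given below. Of the unfolded protein response, 11 genes rose by 0.28 on average (camera adjusted p = 2.64e-05, adjusted p = 0.399 with an estimated correlation), 7 of them when adjusted over the list alone. They include the chaperones HSPA5 (0.54 ± 0.15), CALR (0.36 ± 0.12), DNAJB11 (0.40 ± 0.13) and SDF2L1 (0.54 ± 0.19, SE). The 11 heat shock genes rose by 0.37 (camera adjusted p = 0.00451, adjusted p = 0.734 with an estimated correlation), among them BAG3 (0.94 ± 0.28), HSPA1L (0.50 ± 0.21), HSP90AA1 (0.34 ± 0.16) and HSPH1 (0.61 ± 0.34, SE). Of the heat shock genes 1 was higher when adjusted over the list alone. Over all probes limma called 0 members of these lists, with 7 and 3 at an unadjusted p under 0.05. Without slide 3 the heat shock difference was 0.23 and did not pass.

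Metabolic lists also passed camera's threshold between these groups. The 22 genes of amino acid catabolism rose by 0.20 (camera adjusted p = 0.00419, adjusted p = 0.734 with an estimated correlation), with the aminotransferase gene GOT1 at 0.39 ± 0.12, TDO2 and KMO of tryptophan breakdown at 0.26 ± 0.10 and 0.39 ± 0.15, and CTH at 0.43 ± 0.16 (SE). The 27 respiratory chain genes rose by 0.095 (camera adjusted p = 0.00343, adjusted p = 0.734 with an estimated correlation), with ATP5O at 0.27 ± 0.09, COX6C at 0.23 ± 0.10, NDUFB9 at 0.39 ± 0.17 and NDUFA4 at 0.18 ± 0.08 (SE). Limma called 0 members of either list over all probes and 0 when adjusted over the list alone, with 6 and 4 at an unadjusted p under 0.05. The respiratory chain difference was 0.22 under normexp. Amino acid catabolism did not pass without restricted pigs 7 and 8 (0.11) or without slide 3 (0.18).

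Gluconeogenesis rose by 0.32 over 12 genes (camera adjusted p = 0.0485, adjusted p = 0.734 with an estimated correlation), and periportal hepatocyte markers by 0.40 over 7 genes (camera adjusted p = 0.0485, adjusted p = 0.721 with an estimated correlation). G6PC, which releases glucose, differed by 1.16 ± 0.53, MDH1 by 0.32 ± 0.11 and pyruvate carboxylase PC by 0.24 ± 0.15. The periportal enzyme genes CPS1, SDS and HAL differed by 0.34 ± 0.19, 1.05 ± 0.77 and 0.048 ± 0.07 (SE), beside ARG1, the only member past the threshold over all probes. Adjusted over the list alone, 2 gluconeogenesis genes and 1 periportal gene were higher. Both shifts rested largely on restricted pigs 7 and 8. Without them the differences were 0.052 and 0.16, and neither passed. Without slide 3 they were 0.35 and 0.41, and neither passed.

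Markers of stellate cells and fibroblasts were lower in restricted high RFI than in low RFI pigs. The 14 markers fell by 0.43 on average, 13 of them below 0 (camera adjusted p = 8.09e-05, adjusted p = 0.234 with an estimated correlation), and this was the only list that fry called in any comparison (adjusted p = 0.0157). COL1A2 differed by -0.86 ± 0.20, RGS5 by -1.29 ± 0.30, BGN by -0.38 ± 0.11 and decorin DCN by -0.63 ± 0.28 (SE). Of the markers, 0 passed over all probes, 6 had an unadjusted p under 0.05 and 3 were lower when adjusted over the list alone. The list was lower on all 6 slides, which again follows partly from its choice on these arrays. Markers of some other cells also lay below 0 without passing, at -0.31 for neutrophils (6 of 6 below 0, adjusted p = 0.124), -0.14 for endothelium (11 of 11, adjusted p = 0.176), -0.15 for adipocytes (7 of 7, adjusted p = 0.356), -0.28 for smooth muscle and gallbladder wall (4 of 4, adjusted p = 0.492) and -0.28 for skeletal muscle (8 of 9, adjusted p = 0.215). The 4 measured markers of pancreatic acinar cells fell by 0.95 on average (camera adjusted p = 0.0485, adjusted p = 0.600 with an estimated correlation), with carboxypeptidase CPA1 at -1.81 ± 0.46, elastase CELA2A at -1.72 ± 0.74, colipase CLPS at -0.29 ± 0.15 and amylase AMY2 at 0.021 ± 0.12 (SE). Of these 4, 0 passed over all probes, 2 had an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. The acinar list did not pass without low RFI pigs 7 and 8 (-0.83), without slide 3 (-1.08) or with the pig number as a block (-0.95, camera adjusted p = 0.0587).

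On the separate scan days the unfolded protein response differed between restricted high and low RFI pigs by 0.30 and 0.32, heat shock by 0.69 and 0.16, and amino acid catabolism by 0.29 and 0.091. The respiratory chain differed by 0.20 and 0.035, gluconeogenesis by 0.50 and 0.15, periportal markers by 0.63 and 0.17, stellate markers by -0.33 and -0.57, and acinar markers by -0.48 and -1.12. With slide as a block the differences were 0.31, 0.44, 0.20 and 0.13 for the unfolded protein response, heat shock, amino acid catabolism and respiratory chain. For gluconeogenesis, periportal, stellate and acinar lists they were 0.34, 0.42, -0.43 and -0.84, and the periportal list no longer passed. With scan day as a block the periportal (0.42) and acinar (-0.79) lists did not pass. Gluconeogenesis and periportal lists also did not pass with quantile normalisation (0.28 and 0.37), median centring (0.33 and 0.41), the authors' values (0.33 and 0.42) or array weights (0.29 and 0.39). The respiratory chain (0.053) and acinar (-0.94) lists did not pass with quantile normalisation, nor gluconeogenesis (0.31) and the acinar list (-0.91) with the mean of all probes of a gene.

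**Figure D3:**
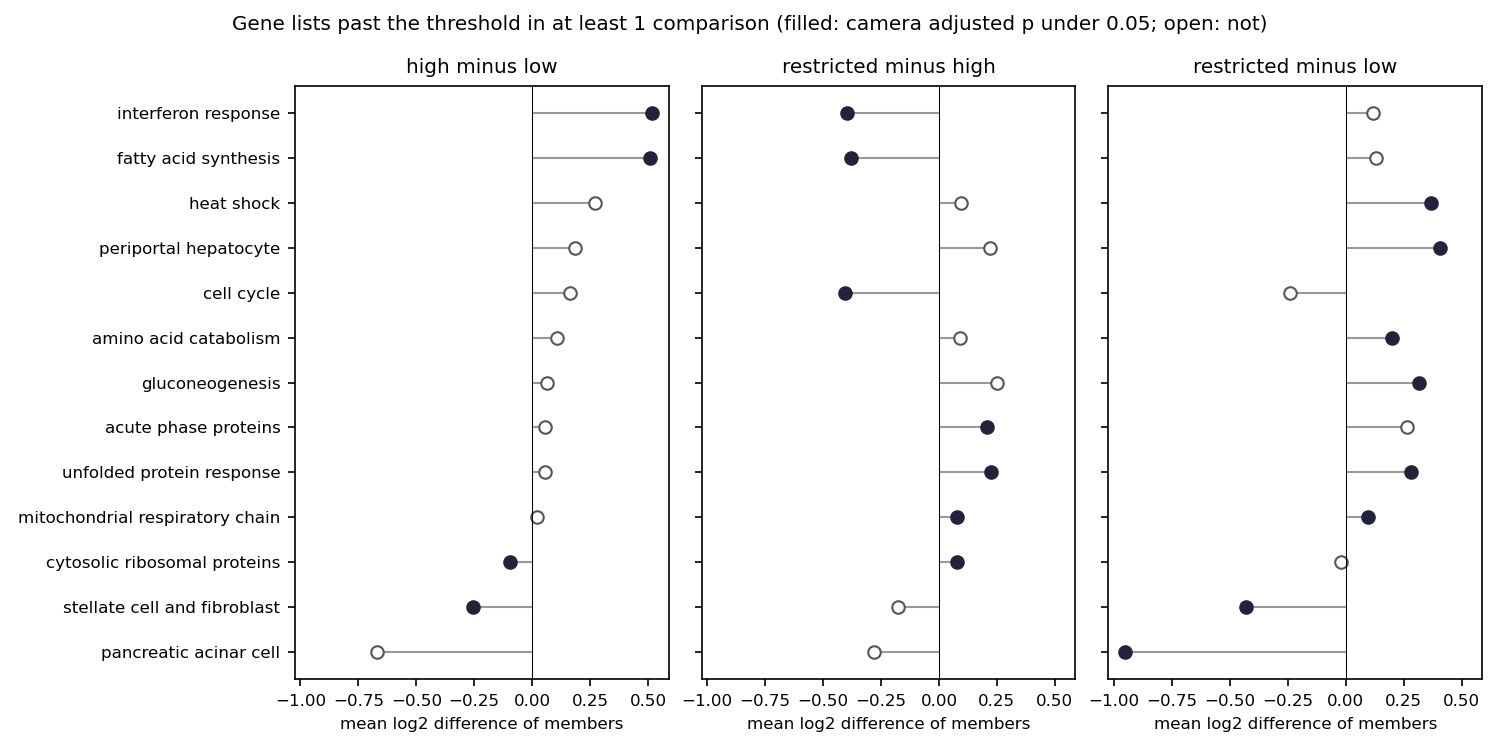
The 13 gene lists that passed camera's threshold in at least 1 comparison, with the mean log2 difference of their measured members on the horizontal axis in each panel. Filled points passed an adjusted p of 0.05 with the preset correlation and open points did not. Fatty acid synthesis lies at 0.51, -0.38 and 0.13 in the panels from left to right, and stellate and fibroblast markers at -0.25, -0.18 and -0.43.

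**Figure D4:**
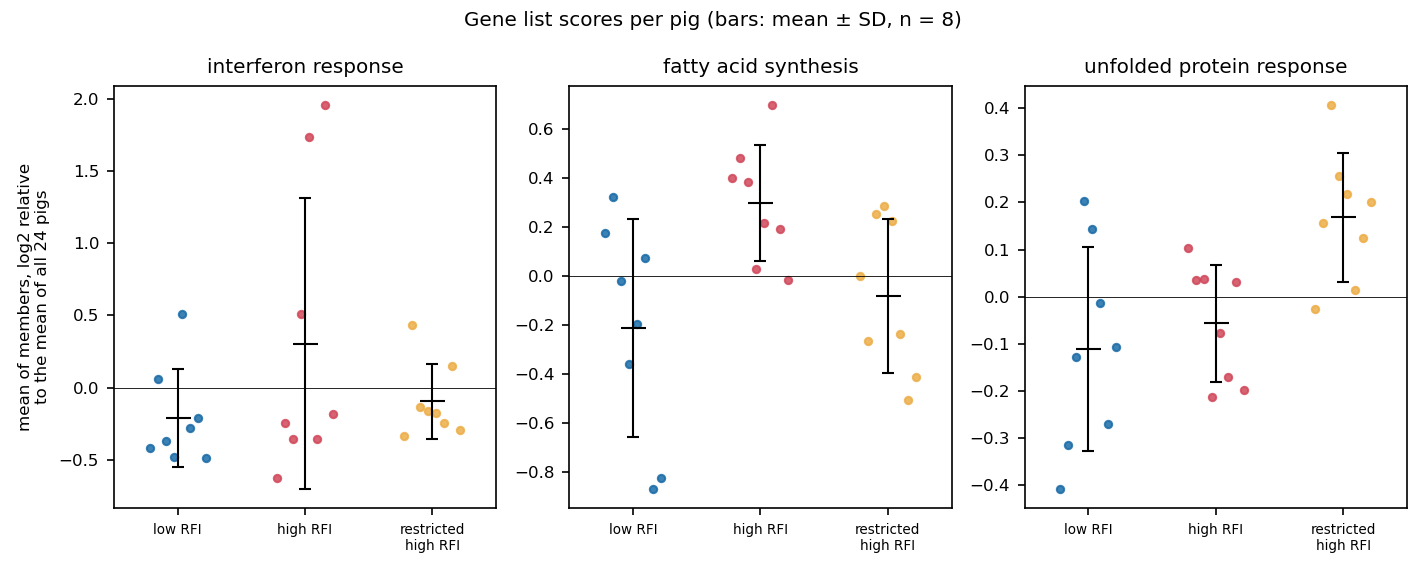
Scores of 3 gene lists per pig, as the mean log2 signal of the measured members relative to the mean of all 24 pigs. Points are single pigs (8 per group), and bars are the mean and SD. In the interferon panel high RFI pigs 5 and 7 lie at 1.74 and 1.96, above all others.

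Of the lists, 4 passed between high and low RFI pigs (2 up, 2 down), 7 between restricted and high (4 up, 3 down) and 8 between restricted and low (6 up, 2 down). Any 2 of these comparisons share a group, so shifts of a list in both are not independent. The lists described passed on these same arrays, so their directions on separate slides and scan days are not separate evidence. With an estimated correlation 0 lists passed in each comparison, and fry called 0, 0 and 1. On the separate scan days 9 and 1, 11 and 5, and 11 and 3 lists passed in these comparisons. Mean, median and test had different signs for 9, 5 and 9 lists, none of which passed. In the order high minus low, restricted minus high and restricted minus low, mean differences of lists that never passed were as follows. Cholesterol synthesis was at 0.068, -0.071 and -0.0024, triglyceride synthesis and lipoprotein assembly at -0.13, 0.099 and -0.030, and fatty acid oxidation and ketogenesis at 0.064, 0.067 and 0.13. The urea cycle was at 0.096, 0.070 and 0.17, and the growth hormone and IGF axis at 0.051, 0.068 and 0.12. Hepatocyte markers were at -0.0038, 0.046 and 0.042, Kupffer cell and macrophage markers at 0.12, 0.044 and 0.16, and T and NK lymphocyte markers at 0.11, -0.040 and 0.065. Neutrophil markers were at -0.41, 0.096 and -0.31.

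Whether restriction moved high RFI liver towards the low RFI profile was addressed by setting low minus high against restricted minus high over all 29665 probes. The differences correlated at 0.27 with a covariance of 0.0139. Because both use the high RFI arrays, 1000 simulated unchanged groups gave a mean covariance of 0.0194 and a mean correlation of 0.49, and 679 of them gave a covariance and 893 a correlation as large as the observed one. With the high RFI arrays split into separate sets of 4, the correlation averaged -0.049 and the covariance -0.0038 over 70 splits, with covariances from -0.016 to 0.0072. These values take restricted and high RFI arrays as independent, whereas same-numbered pigs of these groups deviated together, which lowers the covariance expected without a change. In 1000 simulations with each group drawn from its own arrays and the numbers together, the mean covariance was 0.0145 and the mean correlation 0.41, and 450 gave a covariance and 902 a correlation as large. With the numbers drawn apart these were 0.0170, 0.44, 550 and 851, so part of the lower covariance comes from drawing within groups. The numbers alone would give the splits a covariance of -0.0031. The correlation was 0.22 and 0.17 on the separate scan days. It turned slightly negative under normexp background correction and was higher without a filter, as given below. Correlations are across probes, which are not independent replicates.

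The other pairing, chosen after the data were seen, compared high minus low with restricted minus low, which share the low RFI arrays. These correlated at 0.73 with a covariance of 0.0533, beside a simulated 0.0189, and 5 of 1000 simulated groups gave a covariance and 89 a correlation as large. With the low RFI arrays split, the correlation averaged 0.38 and the covariance 0.0346. Drawn within groups with the numbers of high and restricted pigs together, the simulated covariance was 0.0217, and 17 of 1000 gave a covariance and 148 a correlation as large. With the numbers apart it was 0.0185, with 11 and 66. The numbers alone would give the splits a covariance of 0.0031. OAZ3, UBD, ZAR1L and HPSE were among 16 probes called higher and 11 called lower in both comparisons. Lists of these sizes that shared no array and were independent would share 0.029 and 0.024. In 100 simulated sets of unchanged groups that shared a simulated low RFI group, 0 probes were called in both. With arrays drawn within their own group, 6 of 100 simulations with the numbers together and 7 with them apart called as many as 27. The highest counts were 188 and 380. Both kinds of draw repeat some arrays, which the fit takes as separate pigs, and draws within a group repeat them there more often. None of these simulated counts of probes, here or below, is therefore an exact chance level. All 48 probes called between high and low RFI went in the same direction in restricted pigs, 46 of them at an unadjusted p under 0.05. Of the 66 called between restricted and low RFI, all went in the same direction at free intake, 60 of them at an unadjusted p under 0.05. With a simulated low RFI group shared, the same number of top probes in the unchanged groups averaged 45.1 of 48 and 61.9 of 66 in the same direction. Of these, 17.1 and 21.7 on average had an unadjusted p under 0.05. Of the 100 simulations, 44 and 36 gave directions and 3 and 2 gave unadjusted counts as large as those observed. Drawn within groups with the numbers together, the averages were 45 and 57 in the same direction and 31 and 31.8 at an unadjusted p under 0.05, with 13 and 9 simulations as large for direction and 9 and 3 for the unadjusted counts. With the numbers apart, the averages were 43.8 and 54, and 29.2 and 27.7, with 11 and 2, and 2 and 0 as large. With the low RFI arrays split into separate sets of 4, directions agreed for 42.8 of the top 48 and 59.7 of the top 66 on average, 23.1 and 31.2 of them at an unadjusted p under 0.05.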

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

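The tests of interferon genes, of probe sequence and slide, and of single pigs and hepatocyte share were chosen after the results were seen. Those of other splits of the arrays and of the share of spots above background were chosen before.

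The difference between the lines was the clearest result. Of 100 splits of the 16 high and low RFI arrays into 8 and 8, 1 gave as many probes, the real one with 48, and the highest other gave 2. For restricted high against low RFI it was also 1 of 100, with 66 probes against 4. With 100 splits no share below 1 in 100 can be seen, so chance is unlikely for both but not excluded. The splits also take the pigs as independent, and relatedness within the lines was not tested.

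OAZ3, ZAR1L, RPL14 and the other genes that differed between low RFI and either group of the high RFI line were examined for a sequence variant under single probes. Of 38 other probes for these genes, 92.1% went the same way, which argues against such variants as the whole cause. A slide effect as the whole cause is argued against by 48 of 87 probes that stayed past the threshold with slide in the fit. All 87 kept their direction, which their choice from these same arrays largely fixes. For 7 of 19 genes, among them UBD, SYK and KLF3, no other probe passed an unadjusted p of 0.05 in the same direction, so a variant under the probe and a difference in level cannot be told apart there. A difference in transcript level between the lines remains a hypothesis for the others, and family or relatedness within the lines was not tested.

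Interferon-response genes were higher in high RFI pigs by 0.51. Without pigs 5 and 7 the mean of the list differed from low RFI by 0.00087, over members that went both ways, with GBP1 at 0.51 and CXCL11 at -0.88. The tables argue against a slide effect, since no other array of their slides scored above 0.51 where the lower of the pigs scored 1.74. More T and NK cells and another source cannot be told apart, since the pigs' T and NK scores were 0.37 and -0.10 around a median of 0.0144 in the others (SD 0.26). An infection or another stimulus in these 2 animals was not tested, and the labels give no health data.

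The fatty acid synthesis list was higher on average in high RFI pigs than in both other groups, although 0 of its genes passed limma's threshold over all probes, with 7 and 4 at an unadjusted p under 0.05. Both differences use the same high RFI arrays, so they are not independent results. With the percentage of spots above background as a covariate, 82.0% of the difference from low RFI and 71.9% of that from restricted pigs was left. Both were past camera's threshold at the preset correlation. With an estimated correlation camera called neither even without the covariate (adjusted p = 0.827 and 0.254). The bound written beforehand was 75%, so a part played by the share of spots above background cannot be told apart from feeding and line. The mean 75th percentile of the signal was 423.2 in high RFI, 425.6 in low RFI and 409.6 in restricted pigs. Leaving out any 1 pig left at least 81.6% (without both low RFI pigs 7 and 8 the difference was 0.30). The upper 95% limit of the hepatocyte marker difference from low RFI was 0.0926, below the 0.255 needed. From restricted pigs it was 0.0508, below the 0.19 needed. These values argue against 1 pig and against hepatocyte share as causes. Higher feed intake may account for the pattern, as a hypothesis that the share of chance splits below leaves open.

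For gene lists chance could not be excluded. As many lists as the real 4 passed in 59 of 100 splits for high against low RFI (highest other 12), as many as 7 in 36 for restricted against high (highest other 18), and as many as 8 in 28 for restricted against low (highest other 15). The splits of restricted and high RFI arrays ignore the pig number, although same-numbered pigs of these groups deviated together. For single probes between restricted and high RFI pigs the real count was 0, below which no split can fall, so 100 of 100 (highest other 8) says nothing, and chance and a small difference cannot be told apart. For the F test over the 3 groups, 1 of 100 splits gave as many probes, the real one with 63, and the highest other gave 1.

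Single pigs stood apart from the other 7 of their group in 15 of 229 groups of values tested, where chance gives about 1 in 20 groups, or 11.5. In low RFI pigs, OAZ3 was 0.23 in pig 7, where the others lay between -2.86 and -2.02. That pig also lay towards the high RFI line in UBD (0.39, others -1.22 to -0.36) and in C4H8orf37, the lowest of its group (-1.30). ME1 was -3.79 in the same pig (others -3.19 to -2.76). In pig 8, CLPS was -1.46 (others -2.78 to -2.18), the FADS1 probe A_72_P368958 was 4.64 (others 5.42 to 5.98) and OAS2 was 2.90 (others 4.73 to 5.77). ARG1 was 6.68 in pig 6 (others 5.64 to 6.06), HSP90AA1 was 6.40 in pig 4 (others 5.62 to 5.84) and P2RY1 was -1.78 in pig 1 (others -2.65 to -2.29).

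In high RFI pigs, DNAJB11 was 1.89 in pig 8 (others 2.29 to 2.57) and SPARC was 1.82 in pig 2 (others 3.06 to 3.96). In restricted pigs, pig 3 had ATP5J2 at 6.70 (others 6.21 to 6.38), DNAJB11 at 3.41 (others 2.37 to 2.83) and LBP at 2.21 (others 0.27 to 1.15). KLF3 was 0.20 in restricted pig 4 (others -1.48 to -0.89), and NDUFB9 was 4.44 in restricted pig 1 (others 5.15 to 5.52).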

How the results depend on the processing

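The alternatives that leave out slide 3 or pairs of pigs, and the number block within the high RFI line, were chosen after the data were seen. OAZ3 and UBD kept their calls under every alternative run in both comparisons with low RFI. Of 154 values of the genes that met the rule for naming between high and low RFI pigs, 127 kept direction and side of the threshold, 25 no longer passed and 2 reversed. Between restricted and low RFI the counts were 191, 73 and 2 of 266. Between restricted and high RFI 167 of 168 were as before and 1 newly passed.

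With normexp background correction 5 probes passed between high and low RFI, 13 between restricted and low and 7 by the F test. Of the 48 and 66 probes, 5 and 11 kept their calls, and 46 and 61 their direction. HPSE and SYK reversed to -0.065 and -0.034 against low RFI at free intake and to -0.071 and -0.18 at the restricted level. The correlation of the differences from high RFI reversed to -0.038. Lists passing were 18, 11 and 22 for high minus low, restricted minus high and restricted minus low. The median of all probes moved to -0.107 for restricted minus low under this correction. The cause was not tested, and dim probes are limited by signal over background.

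Without a filter 28 probes passed between high and low RFI and 36 by the F test, and the correlation was 0.42, with more and dimmer probes tested. With array weights 92 passed between high and low and 2 between restricted and high, and the cause was not tested. With fewer arrays, 27 passed between restricted and low with only the 2 groups in the fit, 25 without restricted pigs 7 and 8 and 31 without low RFI pigs 7 and 8. Without slide 3, 28 passed between high and low, 24 between restricted and low and 28 by the F test.

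With an estimated correlation camera called 0, 0 and 0 lists, and fry 0, 0 and 1, in the same order. For restricted minus low, 4 lists passed with quantile normalisation, 3 without slide 3 and 13 without low RFI pigs 7 and 8. For restricted minus high, 4 passed without high RFI pigs 5 and 7, where the interferon list reversed to 0.11. The cause was not tested beyond those pigs' scores. On the separate scan days, with 12 arrays each, lists passing were 9 and 1, 11 and 5, and 11 and 3. Under the other alternatives run on both days together, each count of probes and of lists stayed within 1.5 times its value.

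Whether the pig number pairs samples by design remains open, and the main fit took no pairing into account. Of 24 arrays, 7 correlated best with their own number. Same-numbered high and restricted pigs deviated together (mean correlation 0.14, 5 of 8 pairs over 0.1, 1-sided exact permutation p = 0.00384, adjusted p = 0.0115). In the same exact permutation test, low RFI pigs paired with neither group past the threshold (p = 0.468 with high and 0.365 with restricted). With the number as a block 50, 0 and 93 probes passed in the order above. As a block within the high RFI line alone, 0 probes and 9 lists passed between restricted and high.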

Other observations

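The genes and pigs described here were chosen after their values were seen, and no explanation was tested for them.

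In high RFI pigs 5 and 7 the antiviral gene RSAD2 exceeded the mean of the other high RFI pigs by 4.77 and 5.44 on the log2 scale, and the ubiquitin-like gene ISG15 by 3.96 and 4.54. OAS1, a sensor of double-stranded RNA, exceeded it by 3.81 and 4.33, and IFIT1 by 3.59 and 4.07. In the other high RFI pigs ISG15 differed from low RFI by -0.13.

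The digestive enzyme genes CPA1 and CELA2A, markers of pancreatic acinar cells, varied widely among pigs. CPA1 averaged -0.54 ± 0.80 in low RFI, -1.86 ± 0.91 in high RFI and -2.35 ± 1.16 in restricted high RFI pigs, and CELA2A 0.10 ± 1.75, -1.37 ± 1.55 and -1.62 ± 1.44 (SD, n = 8). Restricted pigs 7 and 8 had the highest scores of all pigs for gluconeogenesis (0.89 and 1.07) and for periportal markers (0.85 and 1.04), and they had the lowest scores of their group for fatty acid synthesis (-0.51 and -0.41).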
